A study of Mus musculus with 3 samples.

How the data were processed

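The series holds ribosome profiling of mouse testis, with 2 libraries labelled as TSCL1 knockout and 1 as wild type. Per the labels' protocols, nuclei were taken from a sucrose gradient, digested with nuclease, and protected fragments were recovered on spin columns. The same text goes on to poly(A) selection, RNA fragmentation and random priming, steps that belong to mRNA libraries. Which of these steps made the present libraries is not settled by the sources used here. A footprint library that was poly(A)-selected or fragmented would not measure ribosome occupancy in the usual way, so "footprint" below follows the labels.

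Per the submitters' processing notes, reads were aligned with HISAT2 to the mouse genome build GRCm38 and assigned to genes with featureCounts. That order of the tools is inferred from what they do, since the notes list names only. Versions, annotation release, selection of footprint lengths, and the strand and multi-mapping settings are not given in the sources used here. Without them, reads of overlapping, antisense or near-identical genes cannot be assigned with certainty. The authors deposited a table of raw counts per Ensembl gene ID, with whole numbers and 1 column per library. The authors also deposited a table of FPKM values for the same IDs. The FPKM tool is not given in the sources used here. In 140 IDs the deposited FPKM was above 0 in a library where the count was 0, including 73 with 0 counts in all 3 libraries, at values up to 0.32. The deposited FPKM values were thus not made from these counts alone.

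Of the 22183 IDs, 0 matched the mouse gene table used for names, whose Ensembl column is empty. The 28 gene lists fixed before the data were examined therefore could not be tested, and no coordinates are given. The rule for named genes, also fixed before, took IDs past the threshold with at least 100 counts in sum whose knockout libraries lay on the same side of the wild-type library by more than their own difference. From these it took up to 12 increases and 12 decreases, ranked by fitted log2 fold change, leaving out names that are only accessions or predicted-gene numbers. That exclusion could not be applied to IDs, and without names only the first 2 in each direction are printed. The parts of the rule on gene lists, on Piwil1 and on the 5 most counted genes could not be used to name genes. The IDs described without being printed were singled out after their values were seen.

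Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, quasi-likelihood F-test, robust fitting off), with genotype as the only term. The TMM factors were 0.951 for KO1, 1.01 for KO2 and 1.04 for WT. Against library totals they shift all log2 differences by 0.13 for KO1 minus WT and by 0.04 for KO2 minus WT. The common biological coefficient of variation was 0.333. Adjusted p-values follow Benjamini and Hochberg, with a threshold of 0.05. CPM were computed from these effective library sizes, and log2 CPM with a prior count of 2, except that the comparison of IDs on or off in 1 library used CPM from library totals. Distances between libraries are medians of absolute log2 differences, with intervals from 200 resamplings of genes, which are not independent replicates. A fold against a genotype at 0 was computed against a floor of 3 counts per library and is a lower bound. Where the knockout genotype was at 0, the floor was averaged in CPM over KO1 and KO2. Ratios with low counts on one side carry exact Poisson intervals on the summed counts.

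The alternatives were DESeq2 1.42.0, other scaling factors, other filters, robust and likelihood-ratio tests, limma 3.58.1 on log2(FPKM + 1) and log2(FPKM + 0.1), removal of the 50 most counted IDs, and random thinning of each library to 13126663 counts. A minimum absolute log2 fold change of 1 was also set on the main calls. Some IDs held identical counts in all 3 libraries. Among IDs with at least 1000 counts in sum, 30 fell into 12 such sets, and among those with at least 30 counts, 310 fell into 140 sets. Called IDs with the same row of 0, 0 and 39 counts numbered 2, so they may count the same reads and are uncertain as separate genes. Figures were drawn with matplotlib 3.10.9.

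The test was run on simulated data with counts drawn for the 16208 IDs at the fitted common dispersion, the same for every ID. Apart from the changed genes, all simulated libraries shared a composition, unlike the data, where KO2 stood apart. Changed genes were drawn only from IDs above a minimum expected count in the smallest library. The recoveries below hold for that simpler setting. For knockout versus wild type it recovered 24 of 50 genes changed 4-fold (48%) and 50 of 50 at 16-fold, at 64-fold and at 256-fold. It also made 16 false calls among these simulated genes, a share of the calls above the nominal one. With no gene changed it made 0 calls. Changes of a few fold can therefore go undetected in this design.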

Results

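Ribosome profiling sequences the RNA pieces that nuclease leaves inside ribosomes, so that the number of reads over a gene follows how many ribosomes its RNA carries. Here it was applied to testes of mice that lack TSCL1, a long noncoding RNA, and to wild-type testis. The series title ties TSCL1 to the translation of target mRNAs through PIWIL1, a testis protein that binds piRNAs. The data held 3 libraries, of which 2 were labelled knockout (KO1 and KO2) and 1 wild type (WT). Total counts over genes were 19827686 in KO1, 31667845 in KO2 and 13126663 in WT. Of 22183 gene IDs, 18053 had at least 1 count in KO1, 18431 in KO2 and 17912 in WT. The median count of the tested genes was 245 in KO1, 408.5 in KO2 and 183 in WT. No matched RNA-seq library was used here, so the values below are footprint abundances and not translational efficiencies.

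The files list genes by Ensembl ID without names, and 0 of the 22183 IDs matched the gene table used for names. The levels of TSCL1 and Piwil1 were therefore not analysed here, and the genotype labels were not checked against the deleted gene. For the same reason no gene is described by its function, and at most 2 IDs are printed in each direction.

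The comparison that the design implies sets knockout against wild-type testis and asks which footprint levels differ without TSCL1. At an adjusted p threshold of 0.05 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjustment), 16 of 16208 tested gene IDs differed, with 10 higher and 6 lower in the knockout libraries. These differences were close to presence against absence. Of the 10 higher IDs, 7 had 0 counts in WT and 3 had between 1 and 20. Of the 6 lower IDs, 5 had 0 counts in both knockout libraries. In each of the 16, both knockout libraries lay at least 2-fold from WT on the same side and farther from it than from each other. The test takes its spread from KO1 and KO2 and so favours such IDs, which means that this carries no separate support.

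The largest fitted increase belonged to ENSMUSG00000104824, with 405 counts in KO1, 560 in KO2 and 0 in WT. Its knockout level was 19.5 ± 2.80 CPM (SD, n = 2), the count scaled to the effective library size, which was at least 88.7-fold higher than WT when WT is set to a floor of 3 counts. Its adjusted p in edgeR was 2.74e-04. ENSMUSG00000096194 had 80 counts in KO1, 331 in KO2 and 0 in WT. Its knockout level of 7.30 ± 4.32 CPM (SD, n = 2) was at least 33.2-fold higher, with an edgeR adjusted p of 0.0149. With KO2 left out, the bound for this gene falls to 19.3-fold. On FPKM values, limma gave it adjusted p-values of 0.987 and 0.967 with pseudocounts of 1 and 0.1, and 0.502 with a mean FPKM of at least 1. Over its 13 alternative tests the adjusted p ran from 2.01e-09 to 0.987. Another gene ID with 8 counts in WT had 356 in KO1 and 649 in KO2, which made it 33.7-fold higher in the knockout libraries (95% exact Poisson interval 17.1 to 78.4).

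The largest fitted decrease belonged to ENSMUSG00000051940, which had 0 counts in both knockout libraries and 412 in WT. The WT count has a 95% exact Poisson interval of 373 to 454. The WT level of 30.2 CPM was at least 239-fold above the floor of 3 counts, taken as its mean CPM over KO1 and KO2. The edgeR adjusted p was 7.48e-06. With KO2 left out the bound was 190-fold, and with KO1 left out 322-fold. ENSMUSG00000117874 also had 0 counts in both knockout libraries, against 181 in WT. Its WT level of 13.3 CPM was at least 105-fold above the same mean floor, with an edgeR adjusted p of 1.39e-04. Here the bound was 83.3-fold with KO2 left out and 141-fold with KO1 left out. Like ENSMUSG00000104824, both of these IDs missed the threshold in limma on FPKM without a filter (adjusted p of 0.987 with a pseudocount of 1 and 0.967 with 0.1) and passed it with a mean FPKM of at least 1. The smallest adjusted p of all tested IDs, 5.14e-07 in edgeR, belonged to a further ID with 3 counts in KO1, 5 in KO2 and 3208 in WT. Its level was 235 CPM in WT, and the WT level was 1493 times the knockout level (95% exact Poisson interval 757 to 3461). The intervals and floors take in counting error only and leave out variation between samples. Reads copied by PCR are not independent molecules, so where such copies were counted the intervals are too narrow even for counting error.

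**Figure D1:**
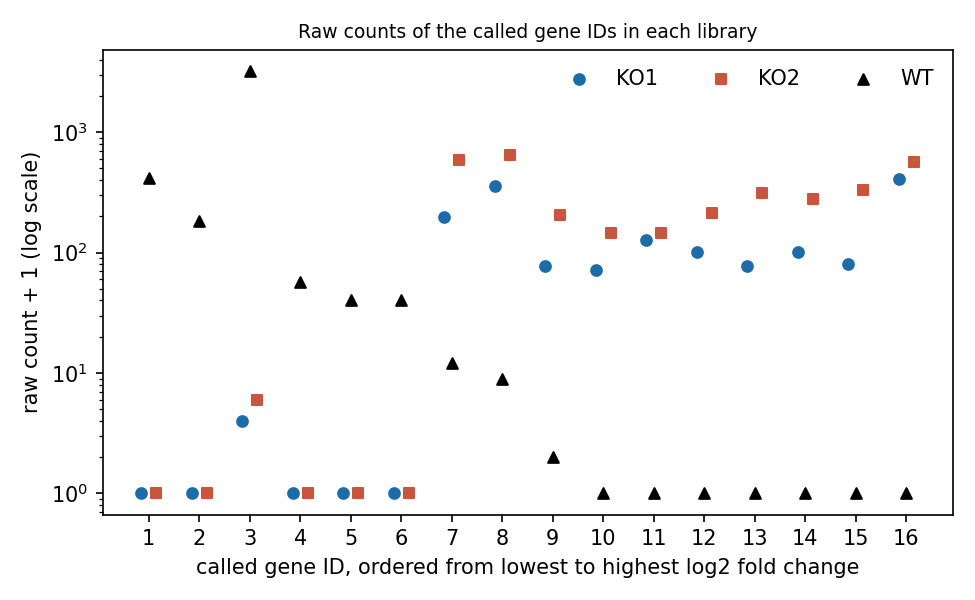
Raw counts plus 1 in each library, on a log axis, for the 16 gene IDs past the threshold, ordered along the horizontal axis from the lowest to the highest fitted log2 fold change (circles KO1, squares KO2, triangles WT). The 6 lower IDs have between 39 and 3208 counts in WT, and the 10 higher IDs have between 71 and 649 counts in each knockout library.

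The test rests on 1 residual degree of freedom, which comes from the difference between KO1 and KO2. The lone wild-type library was assumed to vary as KO1 and KO2 do. With KO1 and KO2 as the pair, the common biological coefficient of variation was 0.333. It was 0.119 with KO1 and WT as the pair, and 0.346 with KO2 and WT. The dispersion was thus higher in both pairs that hold KO2. A low number of calls therefore does not show that a genotype effect is small. Unadjusted p-values under 0.05 numbered 254, below the 810 that chance alone would give over 16208 IDs if the p-values were uniform. With no filter on low counts 68 IDs passed, and with at least 10 counts required in each library 6 did. The dispersion of each ID was also drawn toward that of the other IDs. For the 5 lower IDs with 0 counts in both knockout libraries, these libraries showed no spread. Their p-values thus rest on the dispersion of other IDs. Nothing in the labels says that the knockout libraries came from separate animals, so the spread behind the p-values is that between these samples and may be technical.

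Most other footprint levels in KO1 were close to those in WT, and KO2 stood apart from both. Over the 16208 tested IDs the median absolute log2 difference was 0.17 between KO1 and WT (95% bootstrap interval over genes 0.17 to 0.18). It was 0.43 between KO1 and KO2 (0.42 to 0.43) and 0.45 between KO2 and WT (0.45 to 0.46). Among the 11138 IDs with a mean of at least 100 counts, a filter chosen after the data were seen, 56 (0.503%) lay at least 2-fold apart in KO1 and WT. The number was 1151 (10.3%) between KO1 and KO2 and 1384 (12.4%) between KO2 and WT. The difference between the knockout libraries was thus larger than that between KO1 and WT.

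**Figure D2:**
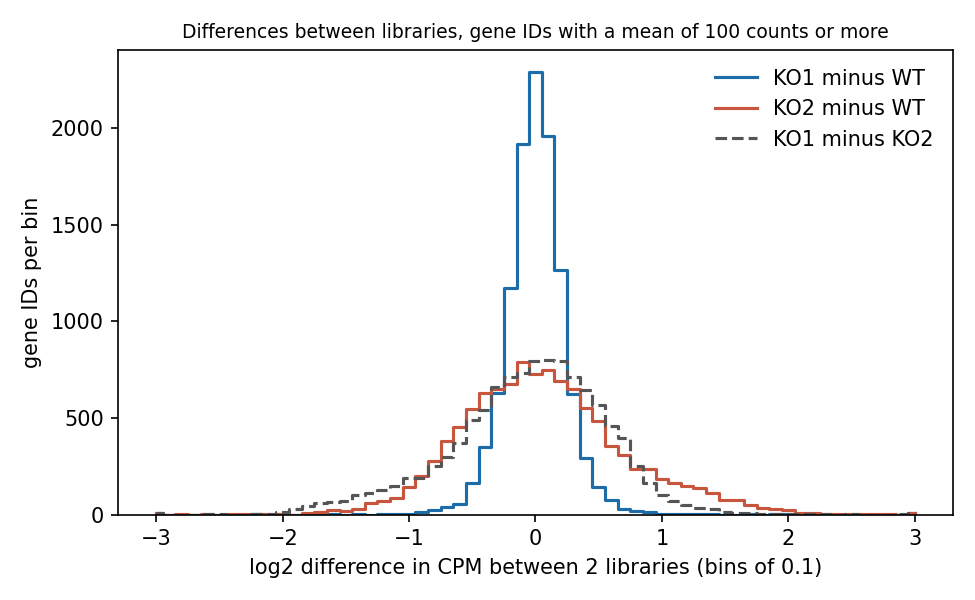
Number of gene IDs per bin of 0.1 in the log2 difference of CPM between 2 libraries, over the 11138 IDs with a mean of at least 100 counts; differences beyond 3 are placed in the outermost bins. The curve for KO1 minus WT is narrow, with a median absolute difference of 0.13, and those for KO2 minus WT (0.40) and KO1 minus KO2 (0.38, dashed) are wide.

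In the most counted genes KO2 also stood apart from both other libraries. The 5 gene IDs with the most counts over all libraries held 25.9% of the counts in KO1 (95% exact binomial interval 25.92 to 25.96), 22.97% in WT (22.95 to 23.00) and 9.590% in KO2 (9.579 to 9.600). All 5 were at least 2-fold lower in KO2 than in each of the others, with a median log2 difference of -1.27 from WT and -1.53 from KO1. The median for KO1 against WT was 0.31, so that WT lay between the knockout libraries in these IDs. Of the 50 most counted IDs, 12 were at least 2-fold lower and 13 at least 2-fold higher in KO2 than in both other libraries, and in 0 of them did KO1 lie 2-fold from WT.

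Of the 11138 IDs, 34 lay at least 2-fold from WT in both knockout libraries, with 25 higher and 9 lower, and 9 of the 34 passed the edgeR test. This count and its filter were added after the data were seen. At a mean of at least 10 counts it was 298 of 15716 (196 higher, 102 lower), and after thinning all libraries to the smallest total, which also left fewer IDs over the filter, it was 20 of 9835 (11 higher, 9 lower). The split of the 34 was the same with relative log expression factors, 19 higher and 11 lower with library totals only, and 16 higher and 19 lower with the deposited FPKM on the log2(FPKM + 1) scale. With KO1 left out, 1384 IDs lay 2-fold from WT in KO2, and with KO2 left out, 56 did so in KO1.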

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

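The identical-row setting, the filter on a mean of 100 counts and every setting of the 2-fold count were chosen after seeing the data. No paired analysis was possible with only 1 wild-type library, which also carries no replicate number. The gene list tests were not run, as no ID had a name. Leaving out either knockout library leaves 1 against 1, which gives values but no test. Against 16 IDs past the threshold (10 higher, 6 lower), 9 of the alternatives gave between 13 and 22 calls, and DESeq2 called 13, of which 12 were shared. Among the 9 is a minimum absolute log2 fold change of 1. It could not change the calls, since all 16 lay beyond it, and carries no support. Relative log expression factors and upper-quartile factors each gave 21 (11 higher, 10 lower). With no filter 68 passed, and with the likelihood-ratio test 32. At least 10 counts in each library left 6, of which 1 was shared, since that filter removes IDs with 0 or a few counts in any library. On FPKM, limma called 0 with a pseudocount of 1 (620 at unadjusted p under 0.05), 0 with 0.1 (681), and 6 with 1 and a mean FPKM of at least 1. The printed IDs passed in 43 of 52 alternative tests, where the 9 losses were all on FPKM (3 for ENSMUSG00000096194, 2 for each of the others). Their direction reversed in 0 of these and in 0 of 8 values without 1 knockout library. Those zeros carry no support. The rule took only IDs with both knockout libraries on the same side of WT, and each printed ID had 0 counts throughout 1 genotype.

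The count of 34 IDs 2-fold from WT in both knockout libraries became 298 at a mean of at least 10 counts, 20 (11 higher, 9 lower) after thinning, and 56 to 1384 with 1 knockout library left out. The distances KO1 to KO2, KO1 to WT and KO2 to WT were 0.40, 0.16 and 0.43 with at least 10 counts in each library, 0.37, 0.12 and 0.39 with at least 100 in each, 0.38, 0.13 and 0.40 with a mean of at least 100, and 0.35, 0.18 and 0.37 on log2(FPKM + 1). With totals only KO1 to WT was 0.21. Except where a filter is named, the cause was not tested. The ratio of the first distance to the second lay between 1.89 and 2.95 in all of these.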

Other observations

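All tests in this part were chosen after the results were seen. The second knockout library, KO2, lay farther from KO1 than KO1 lay from WT, by 2.86 times over IDs with a mean of at least 100 counts. Sequencing depth alone is argued against by a ratio of 2.95 after all libraries were thinned to the same total. Without the 50 most counted IDs the ratio was 2.85. Removing so few IDs can hardly move a median, so this does not decide whether a few genes taking most of the counts played a part. Over all tested IDs the ratio was 2.47 with TMM factors and 2.00 with library totals only. Gene length bias as the whole cause is argued against by a length trend that held 0.605% of the variance of KO1 minus KO2 and left a ratio of 2.83 once removed, with lengths implied by counts and FPKM that differed between libraries by a median of 1.62%. No biological explanation was tested. An effect of TSCL1 loss that differed between the knockout libraries, a difference in tissue makeup or age, a library batch and a wrong label remain open and were not tested.

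The called IDs were at or near 0 in 1 genotype. For the 10 higher IDs, a difference in depth between the libraries is argued against as the whole cause, since 10 still passed in 1 random thinning of all libraries to the smallest total. For 5 of the 6 lower IDs thinning left the counts as they were and tested nothing; their counts of 0 lie in the deeper libraries. The other candidate explanation is that any library differs from the rest in a few genes that are on or off. With identical rows counted in full and a limit in raw counts at unlike depths, this explanation has the number of IDs it needs. That does not hold for all of the called IDs, nor for the level of those on in WT. At 1 CPM or more (from library totals) against at most 3 counts, 34 IDs were on or off in WT alone, 41 in KO1 alone and 44 in KO2 alone, a ratio of 0.8 for WT over the mean of the others. A limit of 3 raw counts is a lower level in a deeper library. Being on alone was thus harder to meet for WT, and being off alone easier. On alone were 12 in WT, 15 in KO1 and 21 in KO2, and off alone 22, 26 and 23. How the ratio changes with a limit at the same level in each library was not tested. Of the 16 called IDs, 13 are among the 34; the other 3 had 5, 8 or 11 counts in a library that had to hold at most 3. The highest level of an ID on in 1 library alone was 31.4 CPM in WT, 12.9 in KO2 and 4.29 in KO1, and the highest level kept by both other libraries for an ID off in 1 alone was 35.7 CPM for KO2, 17.7 for WT and 11.8 for KO1. The limit of 3 counts leaves out the ID with 3208 counts in WT. As folds against the nearer other library with a floor of 3 counts, the largest lone increase was 1548 in WT, 56.4 in KO2 and 18.8 in KO1. The largest lone decrease was 377 in KO2, 78.0 in KO1 and 77.4 in WT. Cut-offs of 2 and 5 CPM were also looked at before 1 was kept, and gave ratios of 0.816 and 0.588. All of these ratios count IDs with identical counts as separate IDs, although such IDs may count the same reads. They occur among the IDs on or off in KO2 alone, among those on in KO1 alone and among those on in WT alone. How the ratios change with each identical set counted once was not tested. Setting 1 library against 2 can be done in 3 ways, too few for a share under 0.05: all 3 gave at least as many calls as the real split, which gave the fewest with 16, against 46 for KO1 alone and 5209 for KO2 alone, the highest. The last number points to a structure of the samples in which KO1 and WT resemble each other.

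Of the 11138 IDs with a mean of at least 100 counts, 718 were at least 2-fold higher and 217 at least 2-fold lower in KO2 than in both other libraries. The numbers were 4 and 17 for KO1, and 9 and 25 for WT. The filter is a mean of raw counts, and KO2 had the largest total with 31667845. An ID high in a deeper library thus passed it more easily than one low in that library. The count of IDs 2-fold from WT in both knockout libraries went from 25 higher and 9 lower to 11 and 9 after thinning. How the split of 718 and 217 changes after thinning was not tested, so it does not show a direction of the KO2 difference. Differences in counting noise alone, simulated for 11154 IDs, gave median absolute log2 differences of 0.05 between KO1 and KO2, 0.06 between KO1 and WT and 0.05 between KO2 and WT.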
